A study of Caenorhabditis elegans with 12 samples.

How the data were processed

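RNA of whole N2 hermaphrodites was sequenced in 12 libraries, 3 in each of 4 groups: worms given 0.1% DMSO, or 100 nM rotenone for 24 h from L4, at 5 or at 15 days of age. The labels give no start or duration for DMSO, do not say whether the rotenone worms received DMSO too, and state neither the event from which age was counted nor how offspring were removed. The labels call the series mRNA and name the kit of the libraries, TruSeq RNA v2, which by its usual protocol selects polyadenylated RNA and does not mark the strand. Each replicate number had a sequencing lane of its own, so that replicates with the same number shared 1 of 3 lanes. Per the labels, the authors used bcl2fastq 1.8.3, STAR 2.4.1d and featureCounts 1.4.6-p4 with the genome build WBcel235, and their settings, annotation release and filters are not stated.

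The authors deposited a table of counts per gene, whole numbers without normalization in 46748 genes and 12 columns, 28963 of which genes had at least 1 count. The authors also deposited a table named RPKM (reads scaled by gene length and library size). Checked against the counts in the 3862 genes with at least 2000 counts in every library, each RPKM value equals its count divided by the gene length and by a library total, but the 12 totals had been repeated down the columns, so that only 8.33% of values were scaled by the total of their own library. Gene lengths implied by the repeated totals differed by at most 0.052% between libraries, while each library's own total gave a median ratio of 1.566 between the largest and smallest implied length. The values are off by factors of 0.639 to 1.566, and the RPKM table was used only as an alternative unit, as deposited and after each value had been rescaled to its own library.

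Gene symbols, chromosomes and positions came from release 115 of the Ensembl annotation of WBcel235, which holds 46449 of the gene identifiers and lacks 299, and genes of mitochondrial DNA were named from the RefSeq table. Library totals were those of the count table. Precision is given as the SD over 3 libraries, or as the standard error of the fit. Members of multicopy families such as histones and the hsp-16 genes share sequence, and the treatment of reads with several matches is not stated, so their single values are uncertain.

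Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 17166, and libraries were scaled with TMM factors. All 12 libraries were fitted in 1 quasi-likelihood model of 4 groups without covariates, and 5 contrasts were tested with the quasi-likelihood F test: rotenone against DMSO at 5 days and at 15 days, 15 against 5 days in DMSO and after rotenone, and the rotenone difference at 15 days minus that at 5 days (the interaction). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in a contrast. The standard error of a log2 difference is its size divided by the square root of F. The biological coefficient of variation was 3.41% over all groups. Pairs of replicates differed by 3.04 to 13.2 times the counting noise (mean chi-square per gene), so that no library was a copy of another. The median chi-square was only 1.23 to 2.33 times its value under counting noise. A typical gene thus lay much closer to counting noise than the mean shows, and the replicates may be technical. Levels in CPM are scaled with the TMM factors, and log2 CPM used a prior count of 2.

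The 35 gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes, except where stated. The lists hold nuclear genes of complex I and of complexes II to V, the protein-coding genes of the mitochondrial genome, the mitochondrial unfolded protein response, cytosolic heat shock, endoplasmic reticulum stress, antioxidant enzymes, glutathione S-transferases, cytochromes P450, UDP-glucuronosyltransferases, DAF-16 class I and class II genes, metallothioneins, the hypoxia response, innate immunity, saposin-like antimicrobials, C-type lectins, collagens, vitellogenins, oocyte and embryo, sperm, histones, body wall muscle, pharynx, neurons, FMRFamide-like peptides, intestine, fatty acid metabolism, glycolysis and gluconeogenesis, the citric acid and glyoxylate cycles, cytosolic and mitochondrial ribosomal proteins, the proteasome, autophagy and lysosome, and the vacuolar ATPase. A list with at least 5 tested members was tested with camera of limma 3.58.1 at its preset correlation between genes of 0.01, two-sided and Benjamini-Hochberg adjusted over the 34 lists of a contrast, and again with an estimated correlation. Counts of members that rose and fell are given adjusted over all tested genes and adjusted over the list alone. fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes, was run as an alternative.

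Named genes were, in each of the 4 comparisons, the 12 largest rises and the 12 largest falls among called genes with a mean of at least 1 CPM and no overlap between the 6 libraries, from each list up to 2 members that rose and 2 that fell in order of adjusted p (or the 2 highest in CPM where no member passed), and always hsp-6, hsp-60, gst-4, sod-3, mtl-1, mtl-2, hsp-4, hsp-16.2, vit-2, nuo-1 and gas-1. For the interaction the 6 largest positive and 6 largest negative values among called genes with a mean of at least 1 CPM were named. Genes called in opposite directions at both ages, and genes named for a test in the closing part, were named after their values had been seen.

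The alternatives were RLE size factors, upper-quartile factors and library totals alone, DESeq2 1.42.0, limma-voom, limma-trend on log2(RPKM + 1), no low-count filter, a filter of at least 5 CPM in 3 libraries, only the groups compared, the sequencing lane as a block, each library left out in turn, a threshold of 2-fold, and a fit without germ line, histone and yolk genes. Rescaled RPKM, a fit without collagens and a fit without both lane 2 libraries of 15 days were added after the data had been seen. Replicate numbers pair samples by lane, which was checked on residuals after group means: their correlation was -0.046 to 0.182 between libraries of the same lane (median 0.017, 18 pairs) and -0.188 to 0.116 between those of different lanes (36 pairs).

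The fit was tested on simulated data, with 50 genes changed at each of 4 folds among 17166 genes of the observed spread. For rotenone at 5 days it found 16% of 1.1-fold, 42% of 1.25-fold, 84% of 1.5-fold and 82% of 2-fold changes, and at 15 days 8%, 50%, 66% and 82%. False calls were 5.66% to 9.92% of all calls over the 5 contrasts, above the adjusted p threshold of 0.05. Few genes were changed in these simulations, and each gene otherwise had 1 mean level in all groups. In the data 44.7% of genes were called for rotenone at 5 days and 76.2% and 79.5% with age. The cut-off of the adjusted p depends on that share, so the simulated shares do not give the recovery or the false calls of these comparisons. camera found a list of 50 genes shifted by 1.1-fold in each contrast. The simulated genes were drawn independently of each other, so this does not show how camera performs where the members of a list are correlated. Every split of the libraries of a comparison into 3 and 3 was refitted, and 60 splits within ages were refitted for the interaction. Correlations across genes are descriptions, since genes are not independent. Further calculations used python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. No library was left out of the main results.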

Results

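Whole hermaphrodites of N2, the wild-type strain of the nematode Caenorhabditis elegans, were sequenced at 2 ages after a brief exposure to rotenone. Rotenone is an inhibitor of complex I of the mitochondrial respiratory chain. It was given at 100 nM for 24 h from L4, the last larval stage. Control worms received 0.1% dimethyl sulfoxide (DMSO), a solvent, for a time that the labels do not state. The 12 RNA-seq libraries formed 4 groups of 3, DMSO and rotenone at 5 days of age and DMSO and rotenone at 15 days. Counts assigned to genes came to 43507026 to 53716605 per library in DMSO and 45612486 to 49375222 after rotenone at 5 days. At 15 days they came to 34307432 to 48687629 in DMSO and 41171323 to 52769067 after rotenone. The 6 vitellogenin genes, which encode yolk proteins, took 5.62 ± 0.146% of the counts in DMSO and 4.00 ± 0.147% after rotenone at 5 days (SD, n = 3). At 15 days they took 1.28 ± 0.078% and 1.24 ± 0.091% (SD, n = 3). The 12 protein-coding genes of the mitochondrial genome took 0.527 ± 0.042% and 0.563 ± 0.042% at 5 days (SD, n = 3). At 15 days these were 0.438 ± 0.043% in DMSO and 0.362 ± 0.019% after rotenone (SD, n = 3). On the first principal component, 82% of the variance parted the 5-day from the 15-day libraries. On the second, with 5%, DMSO worms at 5 days lay at -24.4 to -19.8 and rotenone worms at 5 days at 20.6 to 21.6. The labels do not say from which event age was counted, how offspring were kept out of the samples, or whether replicates came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

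**Figure D1:**
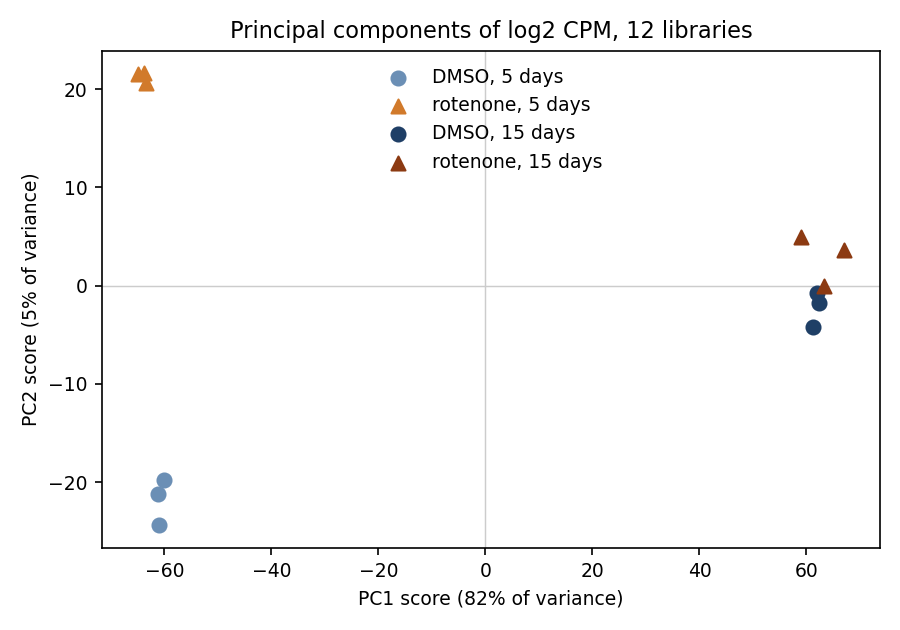
Scores of the 12 libraries on the first 2 principal components of log2 CPM, with the share of variance on each axis and 1 colour or shape per group. Age parts the libraries along the first component (82%), and the rotenone and DMSO libraries of 5-day worms lie apart along the second (5%).

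The first comparison asked how 5-day worms differed after rotenone. The transcript of acs-2 (WBGene00009221, chromosome V, 15567394 to 15569897), an acyl-CoA synthetase that activates fatty acids for oxidation, was 3.35-fold higher, at 116 ± 1.22 counts-per-million (CPM) beside 34.6 ± 1.23 in DMSO (SD, n = 3). hacd-1 (WBGene00019978, chromosome V, 1460369 to 1461613), a hydroxyacyl-CoA dehydrogenase, was 3.51-fold higher, at 97.6 ± 3.53 beside 27.8 ± 1.21 CPM (SD, n = 3). The desaturases that make monounsaturated fatty acids fell, with fat-7 (WBGene00001399, chromosome V, 7151353 to 7153146) at 6.75 ± 0.534 beside 27.4 ± 0.614 CPM (SD, n = 3). fat-5 was at a log2 difference of -1.93 ± 0.05 and fat-6 at -1.19 ± 0.04 (each log2 difference ± the standard error of the edgeR fit). Of the 44 tested genes of fatty acid metabolism, 10 rose and 23 fell (12 and 23 adjusted over the list alone), with a median log2 difference of -0.21 (-0.09 with library totals, where 18 rose and 21 fell). The list passed camera (adjusted p = 0.00401, and adjusted p = 0.16 with an estimated correlation). The largest falls among genes with at least 1 CPM were those of pud-3 (WBGene00017501, chromosome V, 2324634 to 2325152) and pud-4, named for proteins up-regulated in daf-2 insulin receptor mutants. pud-3 stood at 1.6 ± 0.173 beside 22.2 ± 2.12 CPM (SD, n = 3), a log2 difference of -3.80 ± 0.19. pud-4 fell by 3.07 on the log2 scale. The acyltransferase oac-32 (-2.51 ± 0.13), the collagen col-183 (-2.16 ± 0.16) and the lectin clec-43 (-1.87 ± 0.13) fell too. So did folt-2 (-1.86 ± 0.04), of the folate transporter family, C32H11.4 (-2.36 ± 0.20), T28D6.3 (-2.29 ± 0.14) and T12D8.5 (-2.02 ± 0.05). nspe-6 (1.43 ± 0.11) and F40G12.5 (1.88 ± 0.13) were among the largest rises of genes with at least 1 CPM.

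Families of detoxification enzymes held members on each side. The glutathione S-transferases gst-14 (1.74 ± 0.06), gst-30 (1.51 ± 0.12) and gst-12 (1.41 ± 0.08) rose, and gst-6 (-0.67 ± 0.06) and gst-5 (-0.44 ± 0.04) fell. The family had 9 up and 11 down of 42 (10 and 11 adjusted over the list alone, and 14 and 10 with library totals), with a median of -0.02 (0.098 with library totals) and a mean of 0.06. Among cytochromes P450, cyp-13A8 (1.77 ± 0.10), cyp-13A7 (1.63 ± 0.10) and cyp-33C8 (1.32 ± 0.04) rose, and cyp-35A2 (-1.26 ± 0.05) and cyp-37A1 (-0.96 ± 0.05) fell. In all 19 P450 genes rose and 29 fell of 72 (20 and 29 adjusted over the list alone, and 25 and 22 with library totals). UDP-glucuronosyltransferases conjugate lipophilic compounds, and among them ugt-2 (0.95 ± 0.05) rose and ugt-41 (-1.23 ± 0.06) fell. Of 65 members 18 rose and 21 fell (20 and 21 adjusted over the list alone, and 25 and 19 with library totals). The flavin-containing monooxygenase fmo-2 rose by 1.53 ± 0.06. The 3 families did not pass camera (adjusted p = 0.792, 0.321 and 0.896).

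At 5 days 7668 of 17166 tested genes (44.7%) passed, 3662 up and 4006 down (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). Most differences were small, since 115 rose and 133 fell at least 2-fold, and the median size among the genes called was 0.27 on the log2 scale. In 9313 genes (54.3%) the 3 rotenone libraries did not overlap the 3 DMSO libraries, where chance gives 10%. The balance of rises and falls rested on the scaling of libraries. Library totals alone shift the median of all genes from 0.026 to 0.146 and turn the split into 6500 up and 1772 down.

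**Figure D2:**
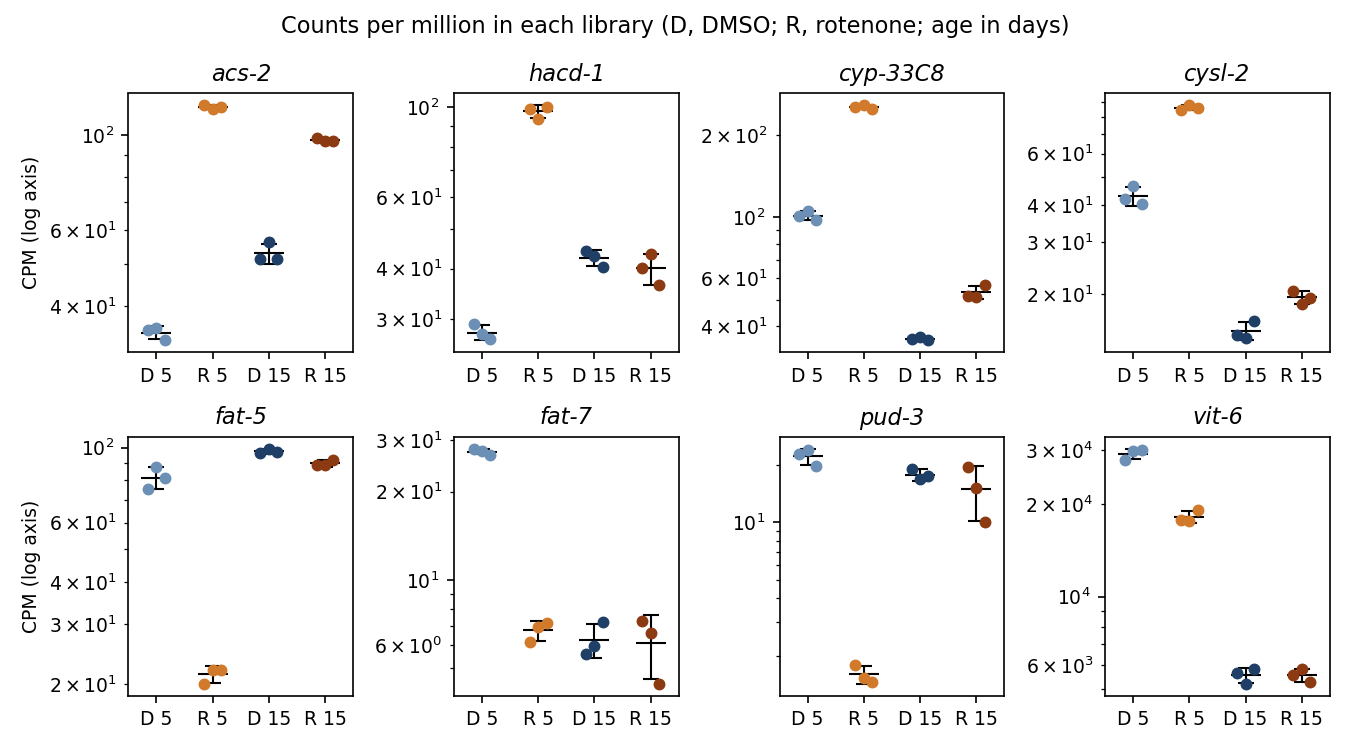
CPM (log axis) of 8 named genes in each of the 12 libraries, by group, with bars for the mean ± SD of 3 libraries. At 5 days acs-2, hacd-1, cyp-33C8 and cysl-2 lie higher and fat-5, fat-7, pud-3 and vit-6 lower after rotenone than in DMSO.

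Nuclear genes of the respiratory chain fell slightly. In complex I, the target of rotenone, 18 of 23 tested subunits fell (19 adjusted over the list alone), with nduf-2.2 at -0.41 ± 0.04 and nduf-11 at -0.23 ± 0.03. nuo-1 was at -0.15 ± 0.03 (-0.03 with library totals, not past), and gas-1 was at -0.01 and did not pass (adjusted p = 0.857). Complex I passed camera with a median of -0.15, or -0.031 with library totals, where 9 fell and 3 rose (adjusted p = 1.73e-06, and adjusted p = 0.29 with an estimated correlation). In complexes II to V 21 of 30 genes fell and 2 rose (23 and 2 adjusted over the list alone), including the complex III subunits ucr-1 (-0.24 ± 0.03) and cyc-1 (-0.21 ± 0.02). Their median was -0.13, or -0.006 with library totals, where 5 fell and 5 rose (camera adjusted p = 0.000109, and adjusted p = 0.482 with an estimated correlation). The 12 genes of the mitochondrial genome did not pass, with COX1 at -0.01 and COX3 at -0.01. The mitochondrial chaperones hsp-6 (0.20 ± 0.03) and hsp-60 (0.23 ± 0.04) and the proteases spg-7 (0.27 ± 0.03) and lonp-1 (0.20 ± 0.03) rose. In all 6 of 13 genes of the mitochondrial unfolded protein response rose (6 adjusted over the list alone, camera adjusted p = 0.0612). In endoplasmic reticulum stress the kinase pek-1 (0.33 ± 0.04) and the chaperone hsp-4 (0.10 ± 0.03) rose, with 10 up and 3 down of 19 (11 and 3 adjusted over the list alone, camera adjusted p = 0.0892). Small heat shock genes split, with sip-1 (0.31 ± 0.05) and hsp-16.2 (0.41 ± 0.08) up and hsp-43 (-0.43 ± 0.06) down. The cytosolic heat shock list had 4 up and 3 down of 16 (4 and 3 adjusted over the list alone, and 8 and 1 with library totals), a median of -0.02 (0.098 with library totals) and a mean of 0.06.

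Among antioxidant enzymes msra-1 (0.41 ± 0.05), a methionine sulfoxide reductase, and the thioredoxin reductase trxr-2 (0.32 ± 0.06) rose. The catalase ctl-2 (-0.60 ± 0.04) and the glutathione peroxidase gpx-2 (-0.32 ± 0.04) fell. In all 5 rose and 13 fell of 30 (7 and 14 adjusted over the list alone), or 11 and 4 with library totals. gst-4, a marker of the SKN-1 oxidative stress response, rose (0.30 ± 0.07, adjusted p = 0.0012). The superoxide dismutase sod-3 did not pass (-0.23 ± 0.10, adjusted p = 0.0688). Among class I targets of DAF-16, the transcription factor of the insulin pathway, 2 rose and 7 fell of 13 (2 and 8 adjusted over the list alone), with fat-5 and mtl-1 (-0.54 ± 0.03) among the falls. Class I targets passed camera with a median of -0.23, or -0.107 with library totals (adjusted p = 0.00376, and adjusted p = 0.168 with an estimated correlation). The other metallothionein, mtl-2, also fell (-0.40 ± 0.04). DAF-16 class II genes are known to be lowered when insulin-like signalling is low. Of the 9 tested, 2 rose and 2 fell (2 and 2 adjusted over the list alone), with a median of 0.02 (0.137 with library totals, -0.007 with RLE factors) and a mean of -0.03. Of 13 genes of the hypoxia response 9 rose (10 adjusted over the list alone), led by the HIF-1 targets cysl-2 (2-fold) and nhr-57 (0.55 ± 0.05). The hypoxia list passed camera with a median of 0.33 (adjusted p = 7.68e-05, and adjusted p = 0.16 with an estimated correlation).

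Yolk, intestinal and immune transcripts were lower after rotenone. All 6 vitellogenins fell (6 adjusted over the list alone), with vit-4 at -1.89 ± 0.09 and vit-6 at -0.68 ± 0.05. vit-2 (WBGene00006926, chromosome X, 5101042 to 5106169) was at -0.40 ± 0.05. Vitellogenins passed camera with a median of -0.95 (adjusted p = 1.08e-05, and adjusted p = 0.266 with an estimated correlation). The intestinal proteases cpr-5 (-1.30 ± 0.05) and asp-5 (-1.13 ± 0.04) fell and the P-glycoprotein pgp-1 (0.61 ± 0.04) rose. Of 19 intestine genes 14 fell and 1 rose (14 and 1 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 3.69e-05, and adjusted p = 0.16 with an estimated correlation). Among 42 innate immunity genes the lysozyme lys-7 (-1.05 ± 0.06) and the infection response gene irg-3 (-1.22 ± 0.09) fell. The lectin clec-4 (0.97 ± 0.09) and the lysozyme lys-3 (0.31 ± 0.07) rose. In all 21 fell and 3 rose (23 and 4 adjusted over the list alone), with a median of -0.30, or -0.175 with library totals (camera adjusted p = 0.000188, and adjusted p = 0.266 with an estimated correlation). The saposin-like antimicrobial gene spp-4 (-1.70 ± 0.08) fell and spp-18 (0.36 ± 0.05) rose. Of 26 saposin-like genes 15 fell and 3 rose (15 and 3 adjusted over the list alone), with a median of -0.29, or -0.167 with library totals (camera adjusted p = 0.0105, and adjusted p = 0.266 with an estimated correlation). Among 138 C-type lectins 42 fell, such as clec-169 (-1.60 ± 0.06), and 22 rose, such as clec-9 (1.85 ± 0.15). These were 42 and 22 adjusted over the list alone, or 33 and 29 with library totals (camera adjusted p = 0.201).

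Muscle, pharynx and neurons differed in direction. The troponin genes tnt-2 (-1.47 ± 0.09) and unc-27 (-1.23 ± 0.07) fell. myo-3 (0.27 ± 0.04), a myosin of body wall muscle, and unc-89 (0.24 ± 0.03) rose. The muscle list had 11 falls and 5 rises of 20 (11 and 5 adjusted over the list alone), with a median of -0.16, or -0.037 with library totals, where 8 fell and 7 rose. It passed camera at adjusted p = 0.0455, but 0.0552 with sequencing lane as a block (adjusted p = 0.776 with an estimated correlation). The pharyngeal myosins myo-1 (0.32 ± 0.04) and myo-5 (0.29 ± 0.03) rose. Of 14 pharynx genes 9 rose (10 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 0.0135, and adjusted p = 0.508 with an estimated correlation). The synaptic genes unc-13 (0.38 ± 0.04) and unc-10 (0.35 ± 0.05) rose. Of 25 neuronal genes 9 rose (9 adjusted over the list alone and 22 with library totals), with a median of 0.15, or 0.269 with library totals (camera adjusted p = 0.000351, and adjusted p = 0.16 with an estimated correlation). The collagens col-121 (0.74 ± 0.06) and dpy-14 (0.62 ± 0.06) rose and col-103 (-0.90 ± 0.07) fell. Of 154 collagens 26 rose and 29 fell (20 and 29 adjusted over the list alone, camera adjusted p = 0.988). The germ granule genes glh-1 (-0.35 ± 0.03) and pgl-1 (-0.31 ± 0.03) fell. Of 38 oocyte and embryo genes 19 fell and 3 rose (19 and 3 adjusted over the list alone), and the median of -0.08 was 0.044 with library totals, where 10 fell and 18 rose (camera adjusted p = 0.0007, and adjusted p = 0.396 with an estimated correlation). Sperm genes had 1 rise, spe-41 (0.95 ± 0.12), and 3 falls of 26 (1 and 2 adjusted over the list alone). Histones had 7 rises, such as his-60 (0.52 ± 0.06), and 3 falls of 30 (7 and 3 adjusted over the list alone). FMRFamide-like peptides had 2 rises and 1 fall of 30, which did not pass adjusted over the list alone.

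Ribosomal protein genes fell by little each. Of 80 cytosolic ribosomal protein genes 65 fell, among them rpl-21 (-0.40 ± 0.03) and rps-18 (-0.37 ± 0.03), and 1 rose (65 and 1 adjusted over the list alone). Their median was -0.20, or -0.083 with library totals, where 40 fell and 10 rose (camera adjusted p = 1.72e-12, and adjusted p = 0.482 with an estimated correlation). Mitochondrial ribosomal protein genes had 41 falls, such as mrps-2 (-0.40 ± 0.03), and 2 rises of 69 (45 and 2 adjusted over the list alone). The median was -0.13, or -0.014 with library totals, where 13 fell and 10 rose (camera adjusted p = 2.37e-08, and adjusted p = 0.16 with an estimated correlation). In the proteasome 19 of 31 genes fell, among them pas-7 (-0.24 ± 0.03) and rpn-11 (-0.24 ± 0.03) (19 adjusted over the list alone). The proteasome median of -0.07 was 0.048 with library totals, where 3 fell and 9 rose (camera adjusted p = 7.66e-05, and adjusted p = 0.482 with an estimated correlation). In the vacuolar ATPase, which acidifies lysosomes, 19 of 20 genes fell (19 adjusted over the list alone), such as vha-9 (-0.28 ± 0.03) and vha-8 (-0.24 ± 0.03). Its median was -0.18, or -0.06 with library totals, where 9 fell and 1 rose (camera adjusted p = 8.62e-07, and adjusted p = 0.16 with an estimated correlation). Glycolysis had 4 rises, led by ldh-1 (0.50 ± 0.05) and aldo-1 (0.37 ± 0.04), and 4 falls of 22 (4 and 4 adjusted over the list alone, and 13 and 1 with library totals). The citric acid and glyoxylate cycles had 3 rises, such as aco-1 (0.42 ± 0.04), and 10 falls, such as idhg-2 (-0.88 ± 0.09), of 22 (4 and 11 adjusted over the list alone, and 10 and 3 with library totals). Autophagy and lysosome genes had 8 rises, such as epg-2 (0.36 ± 0.04), and 5 falls of 27 (8 and 5 adjusted over the list alone, and 17 rises with library totals). The antioxidant, heat shock, DAF-16 class II, sperm, histone, FMRFamide-like peptide, glycolysis, citric acid and autophagy lists did not pass camera (adjusted p = 0.118 to 0.99).

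**Figure D3:**
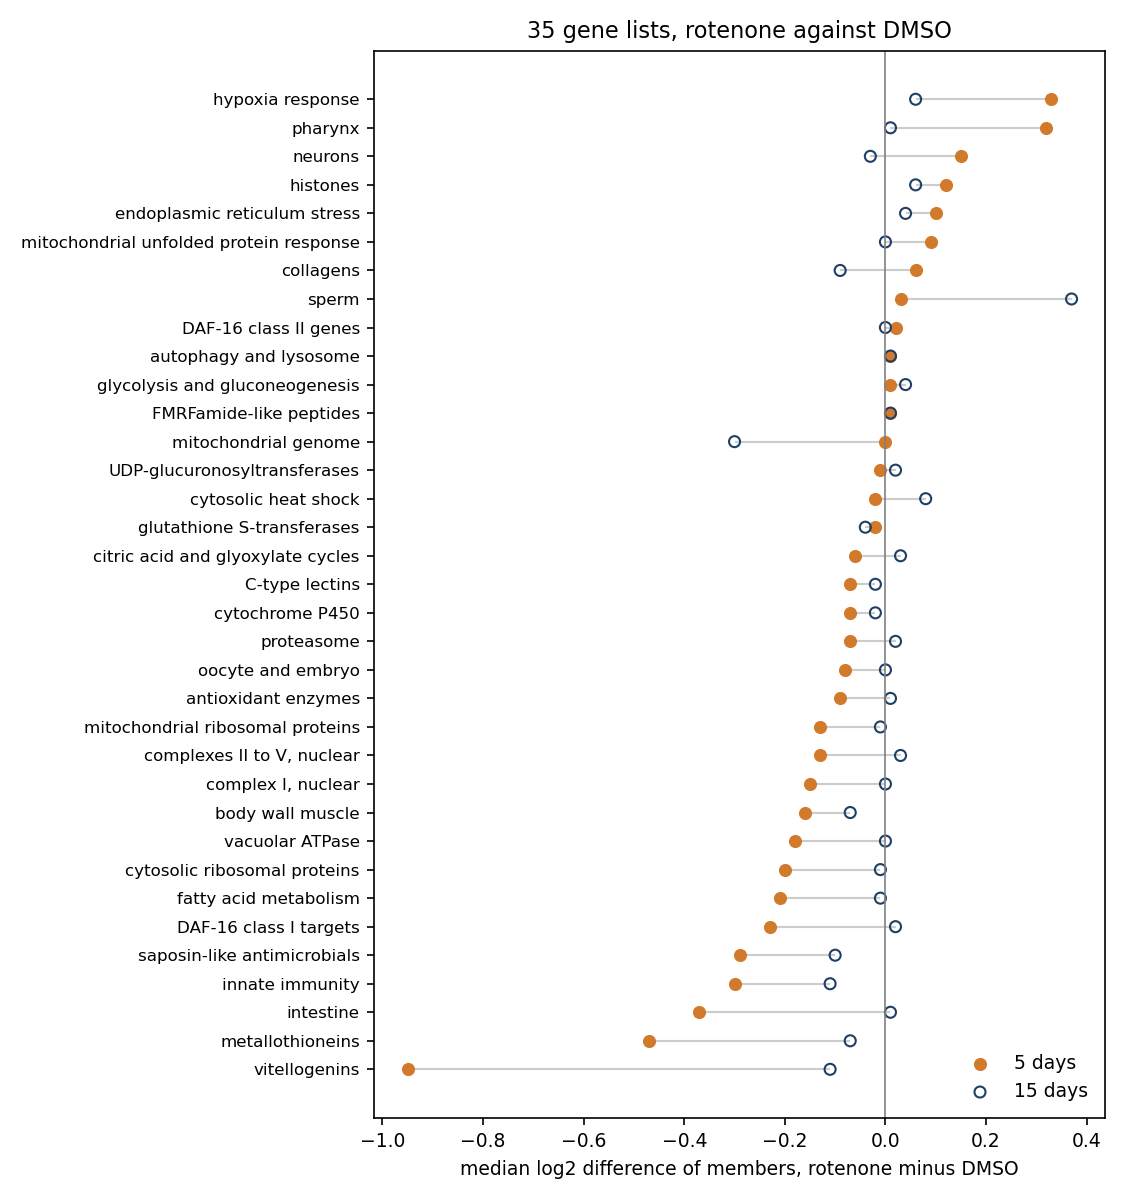
Median log2 difference between rotenone and DMSO of the tested members of 35 gene lists, with filled points for 5 days and open points for 15 days. Vitellogenins (-0.95) lie lowest at 5 days and the hypoxia list (0.33) highest; with library totals alone the 5-day medians of the oocyte, proteasome, antioxidant, P450, lectin and citric acid lists turn positive (0.033 to 0.059), and many medians close to 0 change sign with the scaling.

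The second comparison asked what was left of the rotenone difference at 15 days. acs-2 was still 1.84-fold higher, at 97.3 ± 0.832 beside 53 ± 2.87 CPM (SD, n = 3). fmo-2 (0.77 ± 0.10, adjusted p = 0.000758) and cyp-33C8 (WBGene00019967, chromosome V, 3800782 to 3803542, at 0.56 ± 0.04, adjusted p = 2.58e-07) rose. So did the alcohol dehydrogenase adh-1 (0.54 ± 0.04, adjusted p = 5.03e-07), icl-1 of the glyoxylate cycle (0.46 ± 0.04, adjusted p = 1.49e-06), B0205.13 (0.71 ± 0.07) and B0205.14 (0.63 ± 0.09). Among the falls were ugt-44 (-0.41 ± 0.06, adjusted p = 0.00115) and ZK1290.5 (-0.25 ± 0.04). These 9 genes and the HIF-1 target cysl-2 (0.38 ± 0.06) passed with any 1 of the 6 libraries left out. Of 12 mitochondrially encoded genes ATP6 (WBGene00010960, chromosome MtDNA, 2634 to 3235) and ND4 fell, with log2 differences of -0.34 ± 0.07 and -0.29 ± 0.05 (10 fell adjusted over the list alone). With 1 library of 15 days left out ATP6 lost its call in 3 of 6 fits (adjusted p up to 0.177) and ND4 in 2 (0.104). ATP6 was also not called with only the groups compared (adjusted p = 0.0712) and with at least 5 CPM in 3 libraries (0.0602). The mitochondrial genome passed camera with a median of -0.30 (adjusted p = 1.48e-09, and adjusted p = 0.379 with an estimated correlation). Ribosomal RNA took 1.439 ± 0.513% of the counts after rotenone and 0.935 ± 0.079% in DMSO at this age (SD, n = 3). Nuclear complex I genes lay near their DMSO level (median 0.00, nuo-1 0.00, gas-1 0.06). Hypoxia genes had 2 rises, cysl-2 and cysl-1 (0.22 ± 0.04), of 13 (5 adjusted over the list alone; cysl-1 was lost with any 1 library of 15 days left out, adjusted p up to 0.119), with a median of 0.06 (camera adjusted p = 5.73e-05, and adjusted p = 0.269 with an estimated correlation).

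Named genes lower after rotenone at 15 days also included gpdh-1 (-0.36 ± 0.07), smd-1 (-0.32 ± 0.06), asns-2 (-0.28 ± 0.05), acox-1.5 (-0.30 ± 0.06), pgph-3 (-0.28 ± 0.06), F32H5.3 (-0.51 ± 0.10) and gpx-3 (-0.41 ± 0.09, adjusted p = 0.0563 with lane as a block). The higher ones included mtre-1 (0.79 ± 0.15), F18E3.13 (0.60 ± 0.13) and the collagens col-74 (1.14 ± 0.21) and col-165 (1.47 ± 0.32). Among called genes with a mean of at least 1 CPM and no overlap between the 6 libraries, the largest fall was that of the collagen col-138 (WBGene00000711, chromosome IV, 17182884 to 17183729), at -3.38 ± 0.68. It rested on few reads, at 0.292 ± 0.442 beside 3.55 ± 3.18 CPM (SD, n = 3). limma-voom did not call col-138, col-165, col-74, mtre-1, F18E3.13, F32H5.3, gpdh-1, gpx-3, acox-1.5, pgph-3, spp-12, ugt-2, ATP6 and cysl-1 (adjusted p = 0.0518 to 0.356). DESeq2 did not call gpx-3 (adjusted p = 0.117), ATP6 (0.0726), pgph-3 (0.0716) and cysl-1 (0.0569), and gave no adjusted p for col-138 and F18E3.13. The call of gpx-3 was also lost with any 1 library of 15 days left out (0.0816 to 0.206). Among the 6 fits with 1 library of 15 days left out, acox-1.5 and pgph-3 lost their calls in 5 (adjusted p up to 0.305 and 0.187) and gpdh-1 and F18E3.13 in 4 (0.105 and 0.16). smd-1, F32H5.3, mtre-1 and col-138 lost theirs in 3 (0.113, 0.142, 0.0867 and 0.199), asns-2, aldo-1 and pck-1 in 2 (0.093, 0.0523 and 0.0534) and col-74 in 1 (0.1). Without rotenone_day15 replicate 1 col-165 was at 0.86 (adjusted p = 0.153), and its call was lost too without DMSO_day15 replicates 1 and 3 (0.199 and 0.187). The collagen list had 2 rises and 4 falls of 154 (4 and 9 adjusted over the list alone), median -0.09 (camera adjusted p = 0.00679, and adjusted p = 0.857 with an estimated correlation). Innate immunity had 2 falls adjusted over the list alone and a median of -0.11 (adjusted p = 0.000423, and adjusted p = 0.498 with an estimated correlation). The saposin list had 1 fall, spp-12 (-0.79 ± 0.16), or 3 adjusted over the list alone, and a median of -0.10 (adjusted p = 0.00101, and adjusted p = 0.379 with an estimated correlation). The call of spp-12 was lost without DMSO_day15 replicates 1 and 3 and rotenone_day15 replicates 1 and 2 (adjusted p = 0.103 to 0.182) and with only the groups compared (0.195). Body wall muscle had 1 fall adjusted over the list alone and a median of -0.07 (adjusted p = 0.00183, and adjusted p = 0.767 with an estimated correlation). Cytosolic heat shock genes lay higher (4 rises adjusted over the list alone, median 0.08, adjusted p = 0.000423, and adjusted p = 0.489 with an estimated correlation). Glycolysis had 2 rises, aldo-1 (0.26 ± 0.04) and pck-1 (0.32 ± 0.06), or 4 adjusted over the list alone (median 0.04, or 0.022 with library totals, adjusted p = 0.00127, and adjusted p = 0.767 with an estimated correlation). The citric acid and glyoxylate cycles had 1 rise, icl-1, or 2 adjusted over the list alone (median 0.03, or 0.02 with library totals, adjusted p = 0.00127, and adjusted p = 0.767 with an estimated correlation). Other lists that lay higher were endoplasmic reticulum stress (median 0.04, or 0.025 with library totals, adjusted p = 0.00655), complexes II to V (median 0.03, or 0.013 with library totals, adjusted p = 0.00995) and sperm (median 0.37, most members under 1 CPM, adjusted p = 0.00112). With an estimated correlation the adjusted p of these last 3 lists was 0.767 to 0.803. The other 22 lists tested by camera did not pass, among them vitellogenins (vit-2 at -0.01) and intestine. Median and mean or test differed in sign in the antioxidant (median 0.01, mean -0.02), fatty acid (median -0.01, mean 0.03) and pharynx lists (mean 0.08, camera downward).

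At 15 days 70 genes (0.4%) passed, 48 up and 22 down, 9 of them at least 2-fold, and in 1904 genes (11.1%) the libraries did not overlap, where chance gives 10%. The count changed when single libraries were left out. Leaving out 1 of 3 libraries also lowers the power of the test, and this was not told apart from the influence of that library. For example, ugt-2 lost its call in each such fit but stayed at 0.32 to 0.34, while the estimates of ATP6 and col-138 moved, as given below. It was 31 without DMSO_day15 replicate 1, 45 without rotenone_day15 replicate 2 and 40 without rotenone_day15 replicate 3, and 118 with lane as a block. Of 33 named genes past the threshold 23 lost their call with 1 library left out. Of them 21 lost it without DMSO_day15 replicate 1 (adjusted p up to 0.305), 8 without replicate 2 (0.204) and 12 without replicate 3 (0.187). Without rotenone_day15 replicate 1, 2 and 3, 9, 12 and 17 lost it (0.153, 0.16 and 0.218). ND4 then ranged from -0.32 to -0.25, ATP6 from -0.39 to -0.22 (without DMSO_day15 replicate 1) and col-138 from -6.44 (without rotenone_day15 replicate 1) to -2.34. The markers hsp-6 (0.06), hsp-60 (0.00), hsp-4 (0.06), hsp-16.2 (0.21), gst-4 (-0.12), sod-3 (-0.32), mtl-1 (-0.01) and mtl-2 (-0.12) did not pass.

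The overlap of both ages asked whether the difference recurred. acs-2, cyp-33C8, adh-1, fmo-2, cysl-2 and ugt-2 rose and ugt-44, gpdh-1 and ZK1290.5 fell at both ages. The 15-day call of ugt-2 was lost with each of the 6 libraries of 15 days left out (adjusted p = 0.0695 to 0.09), with library totals (0.0559) and with limma-voom (0.113). That of gpdh-1 was lost without DMSO_day15 replicates 1 and 3 and rotenone_day15 replicates 1 and 3 (0.0806 to 0.105), with limma-voom (0.0561) and with only the groups compared (0.0712). In all 47 genes were called in the same direction, 36 up where 10.2 were expected and 11 down where 5.13 were expected. The shared count was 22 without DMSO_day15 replicate 1 and 28 without rotenone_day15 replicate 3. Opposite directions were called for 8 genes (15.9 expected), among them endu-2 (WBGene00019779, chromosome X, 8242301 to 8247869; -1.03 at 5 days and 0.31 at 15 days). Across all tested genes, which are not independent replicates, the log2 differences at the 2 ages had a Spearman rho of 0.132 and a Pearson r of 0.104. The rho was 0.036 without a low-count filter, 0.253 with at least 5 CPM and 0.064 without rotenone_day15 replicate 1. The 248 genes called and at least 2-fold at 5 days had a median size of 1.23 then and, signed by the 5-day direction, 0.128 at 15 days.

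**Figure D4:**
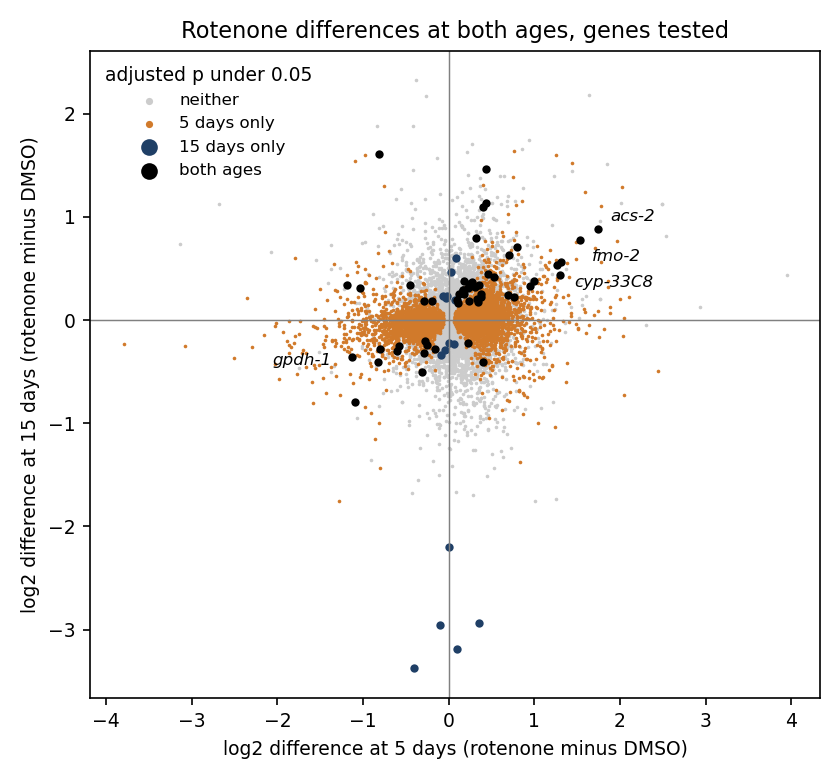
Log2 rotenone difference at 15 days against that at 5 days for the tested genes, coloured by the age at which a gene passed. acs-2, fmo-2 and cyp-33C8 lie above 0 and gpdh-1 below 0 at both ages, and most genes called at 5 days alone lie near 0 at 15 days.

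The interaction asked which rotenone differences changed between 5 and 15 days. The differences of pud-3 (3.56 ± 0.25), pud-4 (2.83 ± 0.20), oac-32 (2.14 ± 0.22) and all 6 vitellogenins (6 adjusted over the list alone, median 0.84) moved up. Those of hacd-1 (-1.89 ± 0.07), gst-14 (-1.65 ± 0.25), cyp-13A7 (-1.68 ± 0.23) and the enoyl-CoA hydratase ech-9 (-1.98 ± 0.18) moved down. They moved up for 16 of 23 nuclear complex I genes (17 adjusted over the list alone, median 0.15, but 4 up, 1 down and a median of 0.019 with library totals) and down for 7 of 12 genes of the mitochondrial genome (10 adjusted over the list alone, median -0.27). Ribosomal RNA took 0.774 ± 0.307% of the counts in DMSO and 0.887 ± 0.329% after rotenone at 5 days (SD, n = 3), beside the shares given for 15 days. Genes of the intestine (12 up and 1 down of 19, 13 and 1 alone, median 0.27, or 0.14 with library totals), of fatty acid metabolism (22 and 8 of 44, 23 and 8 alone, median 0.24, or 0.103 with library totals) and class I targets of DAF-16 (7 and 1 of 13, 8 and 2 alone, median 0.43) moved up. Those of the hypoxia response (7 down of 13, 7 alone, median -0.15, or -0.288 with library totals), pharynx (6 down of 14, 6 alone, median -0.22, or -0.353) and neurons (8 down of 25, 8 alone, median -0.18, or -0.314) moved down. Cytosolic ribosomal proteins (50 up of 80, 61 alone, median 0.20, or 0.065 with library totals, where 19 moved up) and the vacuolar ATPase (17 of 20, 17 alone, median 0.18, or 0.049 and 2) moved up. So did complexes II to V (18 of 30, 22 alone, median 0.15, or 0.011 with library totals, where 3 moved up) and innate immunity (12 up and 4 down of 42, 14 and 4 alone, median 0.16, or 0.024). Mitochondrial ribosomal proteins (29 up and 2 down of 69, 30 and 3 alone, median 0.12, but -0.012 with library totals) and the proteasome (15 up of 31, 20 alone, median 0.10, but -0.035 with library totals) moved up relative to other genes. So did the oocyte list (16 and 2 of 38, 18 and 2 alone, median 0.09, but -0.044 with library totals) and the citric acid and glyoxylate cycles (10 and 2 of 22, 11 and 2 alone, median 0.10, but -0.036 with library totals). These 17 lists passed camera, and with an estimated correlation their adjusted p was 0.162 to 0.531. In all 4419 genes (25.7%) passed, 2643 up and 1776 down, but 939 up and 4296 down with library totals, which shift the median from -0.012 to -0.146.

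The third comparison asked how DMSO worms of 15 days differed from those of 5 days. Since the labels do not state how offspring were kept out of the 15-day samples, the differences are those of the samples as collected. Digestive and detoxifying transcripts were far lower. The cathepsin B-like protease cpr-5 (WBGene00000785, chromosome V, 1132598 to 1134036) fell from 803 ± 43.5 to 18.7 ± 2.18 CPM (SD, n = 3). The log2 differences were -5.47 ± 0.13 and -4.16 ± 0.05 for the aspartyl proteases asp-8 and asp-5, and -4.77 ± 0.07 for the acyl-CoA dehydrogenase acdh-1 (WBGene00016943, chromosome I, 6497436 to 6499560). The short-chain dehydrogenase dhs-26 (5.14 ± 0.09), the adenine nucleotide translocator ant-1.3 (4.45 ± 0.16), scl-20 (5.48 ± 0.33) and Y39A3B.7 (5.65 ± 0.34) were among the largest rises of genes with at least 1 CPM. Other deep falls were those of vmo-1 (-6.04 ± 0.19), the lectin clec-52 (-5.43 ± 0.07), H25K10.1 (-5.68 ± 0.10) and folt-2 (-5.11 ± 0.06). Of 19 intestine genes 18 fell and 1, erm-1 (0.13 ± 0.03), rose (18 and 1 adjusted over the list alone), median -1.79. The glutathione S-transferases (35 down and 1 up of 42, gst-4 at -3.39 ± 0.09), the P450s (55 and 8 of 72, cyp-14A4 at -4.72 ± 0.08) and the UDP-glucuronosyltransferases (50 and 7 of 65, ugt-62 at -3.27 ± 0.05) had medians of -1.26, -1.30 and -1.06. Fatty acid metabolism (35 down and 9 up of 44, acs-2 up by 0.61 ± 0.04) and saposins (24 down of 26, spp-23 at -4.16 ± 0.07) had medians of -0.95 and -1.46. C-type lectins (81 and 28 of 138) and innate immunity (26 and 11 of 42, lys-4 at -4.81 ± 0.06) had medians of -0.86 and -0.58. These lists had the same counts adjusted over the list alone, except for the P450s with 56 down and 8 up.

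Muscle, pharynx and neuron genes fell with age in DMSO, 18 of 20, 14 of 14 and 22 of 25, with medians of -1.03, -1.55 and -0.84. Examples are unc-89 (-1.09 ± 0.03), myo-1 (-1.50 ± 0.04) and the carboxypeptidase egl-21 (-0.89 ± 0.03). FMRFamide-like peptides (27 down and 1 up of 30, median -0.64), collagens (92 and 34 of 154, median -1.45) and the hypoxia list (11 and 2 of 13, median -0.98) lay lower. The vacuolar ATPase (19 and 1 of 20, vha-6 at -2.61 ± 0.05, median -0.50) and glycolysis (15 and 4 of 22, gpd-2 at -1.80 ± 0.04, median -0.29) lay lower too. All 31 proteasome genes rose (rpn-9 at 0.79 ± 0.03, median 0.34), as did 53 of 69 mitochondrial ribosomal protein genes (mrps-18C at 0.74 ± 0.03, median 0.25). Rises were called for 17 of 19 endoplasmic reticulum stress genes (hsp-4 at 0.36 ± 0.03, median 0.36) and 12 of 16 cytosolic heat shock genes (hsp-16.2 at 0.92 ± 0.08 and hsp-12.6 at 2.56 ± 0.17, median 0.40). They were also called for 25 of 38 oocyte and embryo genes (syp-1 at 1.02 ± 0.04, median 0.22), 21 of 30 histones (his-60 at 2.45 ± 0.06, median 0.80) and 21 of 26 sperm genes (spe-6 at 1.44 ± 0.09, median 3.08, most at under 1 CPM). Adjusted over the list alone the counts were the same, except for 93 falls of collagens and 13 rises of heat shock genes. These 23 lists passed camera (highest adjusted p = 0.0401, that of innate immunity, which was 0.0508 with lane as a block), and with an estimated correlation their adjusted p was 0.0593 to 0.512.

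Respiratory chain and yolk genes went both ways with age in DMSO, in lists that did not pass camera. Complex I had 7 up and 6 down of 23 (6 and 6 adjusted over the list alone, nuo-1 at 0.32 ± 0.03 and gas-1 at -0.72 ± 0.04). Complexes II to V had 7 and 17 of 30 (median -0.08, mean 0.00), and vitellogenins 2 and 4 of 6 (vit-3 at 1.74 ± 0.11 and vit-2 at -2.23 ± 0.05). The mitochondrial genome had 5 falls of 12, led by CYTB (-0.66 ± 0.06). The mitochondrial unfolded protein response had 8 rises, including hsp-6 (0.31 ± 0.03) and hsp-60 (0.78 ± 0.04), and 4 falls of 13. Antioxidant enzymes (11 up and 12 down of 30, sod-3 at -0.71 ± 0.11), DAF-16 class I targets (5 and 8 of 13) and class II genes (4 and 2 of 9), the citric acid and glyoxylate cycles (6 and 12 of 22), cytosolic ribosomal proteins (26 and 23 of 80) and autophagy genes (16 and 8 of 27) did not pass either. All but complex I kept these counts adjusted over the list alone. The metallothioneins mtl-1 (-2.85 ± 0.04) and mtl-2 (-0.70 ± 0.05) fell. In all 13078 genes (76.2%) passed, 6050 up and 7028 down (6587 and 6489 with RLE factors), 3961 of them at least 2-fold, and in 13222 (77%) the libraries did not overlap, where chance gives 10%.

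The fourth comparison asked the same of worms that had received rotenone. gst-14 fell from 42.9 ± 1.19 to 0.592 ± 0.0411 CPM (SD, n = 3). ech-9 (-5.06 ± 0.10), clec-52 (-4.76 ± 0.07), cpr-5 (-4.11 ± 0.07) and acdh-1 (-3.92 ± 0.07) fell deeply too. ins-8, an insulin-like peptide (5.33 ± 0.23), dhs-26 (4.43 ± 0.08), ant-1.3 (4.33 ± 0.16) and fat-5 (2.07 ± 0.05) rose. Among nuclear complex I genes 16 rose and 1, gas-1 (-0.65 ± 0.04), fell of 23 (nduf-2.2 at 1.04 ± 0.04, median 0.17, or 0.071 with library totals). All 12 genes of the mitochondrial genome fell (CYTB at -0.81 ± 0.06, median -0.65), and ribosomal RNA took 0.887 ± 0.329% of the counts at 5 days and 1.439 ± 0.513% at 15 days (SD, n = 3). Cytosolic ribosomal proteins had 68 rises and 2 falls of 80 (rpl-11.1 at 0.69 ± 0.03, median 0.20, or 0.104 with library totals). Mitochondrial ribosomal proteins had 64 and 1 of 69 (mrps-18C at 0.83 ± 0.03, median 0.38) and the proteasome 31 rises of 31 (rpn-9 at 0.86 ± 0.03, median 0.43). Heat shock (14 up and 2 down of 16, hsp-110 at 0.50 ± 0.03, median 0.55) and endoplasmic reticulum stress genes (16 and 2 of 19, median 0.29, or 0.189 with library totals) lay higher. So did oocyte (28 and 3 of 38, median 0.30), sperm (21 up of 26, median 2.90) and histone genes (22 and 4 of 30, median 0.62). Detoxification families lay lower. In them 35 of 42 glutathione S-transferases fell and 1 rose (gst-4 at -3.81 ± 0.09, median -1.48), with 56 and 8 of 72 P450s (cyp-33C8 at -2.25 ± 0.04, median -1.16) and 48 and 9 of 65 UDP-glucuronosyltransferases (median -1.12). Intestine (18 down and 1 up of 19, median -1.62), fatty acid metabolism (34 and 8 of 44, median -0.67), saposins (25 down of 26, median -1.48) and lectins (81 and 29 of 138, median -0.85) lay lower too. The same held for hypoxia (12 and 1 of 13, median -1.09), collagens (97 and 23 of 154, median -1.49), glycolysis (14 and 3 of 22, median -0.29) and the vacuolar ATPase (18 and 1 of 20, median -0.36). Muscle (16 down and 3 up of 20, myo-3 at -1.71 ± 0.04, median -0.91) and pharynx (14 down of 14, median -1.74) lay lower, as did neurons (24 and 1 of 25, unc-13 at -1.24 ± 0.04, median -1.09) and FMRFamide-like peptides (27 and 1 of 30, median -0.67). Adjusted over the list alone the counts were the same, except for 70 rises of cytosolic ribosomal proteins and 22 rises of collagens. These 25 lists passed camera (highest adjusted p = 0.0157, that of glycolysis), and with an estimated correlation their adjusted p was 0.0703 to 0.509.

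Lists that did not pass in the rotenone worms held members on each side. Examples are vit-4 (2.04 ± 0.09) and vit-2 (-1.83 ± 0.05) of the vitellogenins (2 up and 3 down of 6, median -0.64, mean 0.02). Complexes II to V had 16 up, such as ucr-2.3 (1.16 ± 0.03), and 7 down of 30 (11 and 11 with library totals). Further examples are hsp-60 (0.55 ± 0.04) and dve-1 (-1.09 ± 0.05) of the mitochondrial unfolded protein response (9 and 4 of 13). Others were antioxidant enzymes (13 and 13 of 30, median -0.08, or 0.008 with RLE factors, with camera upward) and innate immunity (13 and 23 of 42). DAF-16 class I (5 and 8 of 13) and class II (4 and 4 of 9, median -0.11, mean 0.23), the citric acid and glyoxylate cycles (8 and 8 of 22, or 7 and 12 with library totals) and autophagy (16 and 7 of 27, or 9 and 11 with library totals) did not pass either. Adjusted over the list alone, innate immunity had 24 falls and the citric acid and glyoxylate cycles 7, with the other counts the same. The metallothioneins mtl-1 (-2.33 ± 0.04) and mtl-2 (-0.41 ± 0.05) fell. In all 13647 genes (79.5%) passed, 6276 up and 7371 down, 4149 of them at least 2-fold, and library totals shift the median of all genes from -0.091 to -0.191. In 13963 genes (81.3%) the libraries did not overlap, where chance gives 10%. Between the DMSO and rotenone worms 11532 genes were called with age in the same direction, 5317 up (2212 expected) and 6215 down (3018 expected), among them cpr-5, acdh-1 and dhs-26, and 230 in opposite directions (5167 expected). Across genes, which are not independent replicates, both age differences had a Spearman rho of 0.915 and a Pearson r of 0.922 with each other.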

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

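The test of the spread at 15 days was chosen after the counts of called genes had been seen, and the test of depth before. The genes and lists named here stood out because the rotenone difference itself differed between 5 and 15 days by the interaction test, or because a gene was called in opposite directions at both ages.

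The interaction was called for 4419 genes. Among called genes with a mean of at least 1 CPM, the rotenone difference moved up most for pud-3 (3.56), pud-4 (2.83), the collagens col-139 (2.64) and col-81 (2.3), C32H11.4 (2.57) and oac-32 (2.14), and moved down most for ech-9 (-1.98), ZK180.6 (-1.96), hacd-1 (-1.89), F40G12.5 (-1.82), cyp-13A7 (-1.68) and gst-14 (-1.65), all on the log2 scale. The call of col-81 was lost without DMSO_day15 replicate 2 (2.16, adjusted p = 0.0527), DMSO_day15 replicate 3 (2.13, adjusted p = 0.0706) and rotenone_day15 replicate 2 (1.24, adjusted p = 0.0883), and with DESeq2 (adjusted p = 0.0742) and limma-voom (0.174), which did not call col-139 either (0.0547). Without rotenone_day15 replicate 2 col-139 was at 1.39 (adjusted p = 0.0202), and without DMSO_day15 replicate 1 ZK180.6 was at -1.02 (adjusted p = 0.0234), so each rests in good part on 1 library. By camera 17 lists passed for the interaction, 13 of them up and 4 down, with adjusted p of 0.162 to 0.531 with an estimated correlation. Of 60 splits of the libraries within ages 6 called as many genes, with a highest other count of 4941. Splits that kept the true groups at 5 days gave 4145 to 4941 calls, so the interaction rests on the difference at 5 days, whichever way the 15-day libraries were grouped. Those that did not gave at most 1, but they put the 5-day difference into the spread of the fit, so this low count was fixed.

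Opposite directions were called at both ages for 8 genes. The transcript of endu-2, a secreted endoribonuclease, was at -1.03 at 5 days and 0.31 at 15 days (difference 1.34), the peroxisomal thiolase daf-22 at -0.28 and 0.18 (0.47), pho-9 at -1.19 and 0.34 (1.53), the fatty acid amide hydrolase faah-2 at -0.19 and 0.19 (0.38), C23G10.11 at -0.82 and 1.61 (2.43) and C29F7.2 at -0.45 and 0.34 (0.79). srap-1 was at 0.23 and -0.22 (-0.46) and gpx-3 at 0.40 and -0.41 (-0.81). Of the 8, endu-2 alone kept its 15-day call with each of the 6 libraries of 15 days left out. That of daf-22 was lost without DMSO_day15 replicate 1 (adjusted p = 0.0779) or 2 (0.0593), without rotenone_day15 replicate 3 (0.0712) and with only the groups compared (0.0667). pho-9 was lost without DMSO_day15 replicate 1 or rotenone_day15 replicate 1 (0.0993 and 0.0787), C23G10.11 without DMSO_day15 replicate 2 or 3 or rotenone_day15 replicate 2 (0.0507 to 0.0534), and gpx-3 with any of the 6 (0.0816 to 0.206). faah-2 and C29F7.2 were lost without DMSO_day15 replicate 1 or 2 or rotenone_day15 replicate 2 or 3 (0.052 to 0.251), and srap-1 without DMSO_day15 replicate 2 or 3 or rotenone_day15 replicate 2 or 3 (0.123 to 0.235). Chance would give 15.9 genes in opposite directions, so 8 is not an excess. The count was 3 without DMSO_day15 replicate 1 or 2, 4 without rotenone_day15 replicate 2, 5 without any 1 rotenone library of 5 days, and 43 beside 41.7 expected without a low-count filter.

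The weighed pattern is that 70 genes were called for rotenone at 15 days beside 7668 at 5 days. Lower depth is argued against, since the 5-day libraries thinned to the 34307432 counts of the smallest 15-day library still gave 6992 calls (3234 up and 3758 down). A larger spread at 15 days is argued against as the whole cause, because the genes called at 5 days had a median log2 difference of 0.014 at 15 days when signed by their 5-day direction (quartiles -0.026 and 0.064), against 0.265 at 5 days. Of the 248 genes at least 2-fold different at 5 days, 166 (66.9%) kept their sign, 162 (65.3%) passed the interaction test and 9 were called at 15 days. A smaller rotenone difference in older worms may therefore underlie the low count, as a hypothesis, and whether age, the longer time since exposure or survival of part of the worms accounts for it was not tested.

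The other splits of 3 against 3 libraries are too few for a share under 0.05: 1 of 10 splits, the real one, gave as many genes in each comparison. For rotenone at 5 days the real split called 7668 and the highest other 0 by edgeR, where 8776 genes had an unadjusted p under 0.05 in the real split. For rotenone at 15 days the values were 70 and 27, for age in DMSO 13078 and 0, and for age after rotenone 13647 and 0. A split that mixes the groups puts their differences into the spread of the fit. Where the groups differ in many genes, the counts of 0 were therefore fixed and do not measure what chance gives. Among the 3 other splits that part all 3 lane pairs, the highest counts were 0, 5, 0 and 0, and the split with 27 parts 1 pair, setting DMSO_day15 replicates 1 and 2 with rotenone_day15 replicate 1 against the rest.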

How the results depend on the processing

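The rescaled RPKM, the fit without collagens and the fit without both lane 2 libraries of 15 days were chosen after the data had been seen. acs-2, hacd-1, fat-5, fat-7, cyp-33C8 and cysl-2 kept their direction and call at 5 days under every scaling and with any 1 library left out. Of 525 values of named genes, 511 were unchanged with library totals, 518 with RLE factors, 519 with upper-quartile factors, 509 with DESeq2, 506 with limma-voom, 523 without a low-count filter, 524 with lane as a block and 336 with the RPKM as deposited. Unchanged means the same direction and call, or no call in either fit, whatever the sign. With libraries left out in turn, 3115 values were unchanged and 107 lost the call. The losses fell mostly on rotenone at 15 days, where 23 of 33 called named genes lost their call in at least 1 fit. For rotenone at 5 days 8 of 132 did so, with age in DMSO 1 of 147 and with age after rotenone 0 of 144. Among named genes and lists the block ended the calls of gpx-3 at 15 days, body wall muscle at 5 days and innate immunity with age in DMSO. Among all genes 7581 of 7668, 69 of 70, 13009 of 13078, 13589 of 13647 and 4336 of 4419 calls were kept with it.

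Directions reversed in few genes. At 5 days gas-1, at -0.01 with TMM factors, was at 0.114 with library totals and with rescaled RPKM, and ero-1 was at 0.005 with library totals, 0.001 with RPKM as deposited and 0.005 with rescaled RPKM. With RPKM as deposited egl-9 (-0.017) and erm-1 (-0.086) reversed with age in DMSO and hsp-6 (-0.033) with age after rotenone, where values carry the total of another library. For antioxidant enzymes with age after rotenone, fry pointed down with adjusted p = 0.000907 where camera pointed up.

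For rotenone at 15 days, with 70 genes in the reported fit, counts were 322 without a low-count filter, 40 with limma-voom, 118 with lane as a block, 45 with only the groups compared, 38 with rescaled RPKM, and 31 to 77 with 1 library left out. The 47 genes shared with 5 days became 189 without a filter, 69 with lane as a block, 30 with limma-voom, 30 with rescaled RPKM and 22 to 53 with 1 library left out. The correlation of 0.142 between the rotenone difference at 5 days and the age difference in DMSO became 0.373 without a filter, 0.099 with at least 5 CPM and 0.116 to 0.196 with 1 library left out. Apart from the fits with fewer libraries, the cause was not tested. With a 2-fold threshold 248, 9, 3961, 4149 and 234 genes passed (rotenone at 5 days and 15 days, age in DMSO and after rotenone, interaction). The filter at 5 CPM, which tests fewer genes, gave 9062 for age after rotenone. The RPKM as deposited gave 473, 6, 7493, 8195 and 64 genes, with 0 shared by the rotenone comparisons (limma-trend) and 6556 by the age comparisons. With an estimated correlation 0 lists passed camera in each of the 5 contrasts, where fry gave 22, 1, 31, 33 and 19.

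Simulated 1.5-fold changes were found in 60% to 84% of genes over the 5 contrasts and 1.1-fold changes in 0% to 16%. Few genes were changed in those simulations, as few were called for rotenone at 15 days. Small differences at 15 days are therefore not excluded by a missing call. Intervals and standard errors do not cover errors shared by all libraries of a group.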

Other observations

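The scaling tests of both patterns weighed here, and the list of late-embryo cuticle genes, were chosen only after the values had been seen, and the embryo regulators and the further fasting genes were fixed before their 5-day values had been seen. The 16 cuticle genes of late embryos were picked because members had been seen to rise, so their counts describe these genes and do not test a theme, and the collagen list fixed beforehand had camera adjusted p = 0.988. Of the 16 genes 14 rose after rotenone at 5 days, among them noah-1 (0.52), fbn-1 (0.60), lpr-3 (0.64), the patched-related ptr-4 (0.69), mlt-11 (0.62) and the collagen dpy-7 (0.65), with a median log2 difference of 0.54. At 15 days their median was 0.07, and with age in DMSO 13 of the 16 fell, with a median of -0.99.

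Over the scalings the median of these 16 genes was 0.52 to 0.66. The check was chosen after the rise had been seen, and the scalings moved the median by little beside its size. Its outcome was therefore fixed, and it is not a test of scaling as a cause. More embryos of all stages within the rotenone worms stay open: of 30 tested regulators transcribed in early and mid embryos 15 rose and 2 fell (22 rose with library totals), and their median of 0.2 (interval 0.17 to 0.34) spans the boundary set for deciding. In the oocyte and embryo list fixed beforehand, most called members fell at 5 days, but more rose than fell with library totals. That list also holds germ cell and oocyte genes, so it does not decide the question. A higher number of late embryos in the rotenone worms, or cuticle synthesis by the worms themselves, may explain the rise, as hypotheses that these libraries of whole worms cannot part. A biological difference in egg laying was not tested, and the labels do not say how offspring were removed.

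The lipid genes acs-2, hacd-1, fat-5 and fat-7 moved at 5 days as they are known to do in fasted worms. Over the scalings the 4 genes kept direction and call, with a smallest absolute log2 difference of 1.72. The scalings moved them by little beside their size, with acs-2 at 1.72 to 1.87. Since the check was chosen after the values had been seen, its outcome was fixed, and it is not a test of scaling as a cause. A fasting-like change of lipid genes as a whole is argued against by 13 further fasting genes, of which 3 passed in the fasting direction (acdh-1 -1.16, acdh-2 -0.56, fat-2 -0.36), 3 passed in the opposite direction (cpt-3 -0.40, acdh-9 -0.43, ech-6 -0.61) and 7 did not pass. These 13 genes were counted with TMM factors alone. Among those that did not pass, fil-2 (0.236 CPM), lipl-3 (1.28), fil-1 (3.13) and lbp-8 (3.66) had few reads, so their missing calls say little. The genes acs-2, hacd-1, fat-5 and fat-7 therefore may share another regulation, a hypothesis that was not tested.

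The rotenone difference at 5 days was also set beside the age difference in DMSO, which shares the DMSO libraries of 5 days. Across genes the correlation was 0.142, and it was 0.373 without a low-count filter, 0.099 with at least 5 CPM and 0.116 to 0.196 with 1 library left out. In 20 simulated data sets without any effect the shared libraries alone gave 0.428 to 0.548, a value that cannot be compared with 0.142, since real differences add variance and lower a correlation. The covariance was 0.0509 beside a simulated mean of 0.0228 (0.019 to 0.0282), for the genes of the reported fit. Genes called in both comparisons leaned the other way, with 3530 in opposite directions (2911 expected). Both differences were up in 1140 (1291 expected) and down in 1746 (1640 expected). These expected counts take no account of the shared libraries. Covariance and calls point different ways, so no common direction is concluded.

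DMSO_day15 replicate 2 lay apart from the other libraries on the third principal component (2.6% of the variance), at 31.1. On the fourth (2.3%) DMSO_day15 replicate 1 lay at -21.5 and rotenone_day15 replicate 3 at 21.5, the 2 ends of that component. Ribosomal RNA took 0.458% to 2.011% of the counts of a library, and the 10 most abundant genes took 9.27 ± 0.52% and 7.66 ± 0.309% in DMSO and rotenone worms at 5 days and 5.45 ± 0.075% and 5.94 ± 0.544% at 15 days (SD, n = 3).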
